A study of Mus musculus with 15 samples.

How the data were processed

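Sperm DNA of male C57BL/6 mice of generation G1 was profiled by reduced representation bisulfite sequencing, in which the enzyme MspI cuts at CCGG, short CpG-rich fragments are sequenced after bisulfite conversion, and unconverted cytosines are read as methylated. There were 15 libraries, 7 from the control diet and 8 from the protein restricted diet, grouped by the diet given in the labels. The labels do not say whether the diet was eaten by the sampled mice or by a parent, nor which libraries share a mouse, a dam or a batch, and nothing in them says more than that the libraries are separate samples, so p-values measure the spread between these libraries. Replicates are numbered in accession order within a diet and pair nothing.

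The deposited files give, per CpG position, a count of methylated reads and a count of all reads, as raw counts with no normalization. Bismark 0.7.12, Bowtie2 2.1.0 and the mouse build mm10 are named in the submitters' processing notes, which do not give their roles, and the trimming, filtering and merging of strands are not given in the sources used here. Every file lists the same 204492 positions. Every listed position has at least 11 methylated reads in every library, and the rule behind this is not given in the sources used here. A list of this kind leaves out, at ordinary depth, CpGs with little methylation in any library, while deep positions can stay listed with almost none (28 had a mean under 10%), and it makes the coverage minimum of 10 reads, without effect.

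Depth was measured as the sum of read counts over the listed positions, which counts a read once for each CpG it covers. It ranged from 6650912 in protein restricted replicate 6 to 11841657 in control replicate 4, and the median coverage of a position from 26 to 42 reads. At the median coverage, the 95% half-width of counting error for a position at the middle of the scale is between 15.1 and 19.2 percentage points, by the normal approximation. Reads carried no molecular identifiers, so such widths cover counting error only. No pair of libraries had identical counts, and the mean chi-square per CpG between libraries lay between 1.07 and 1.85 over 105 pairs.

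Percent methylation is methylated counts over total counts. Each CpG was tested with a quasi-binomial logistic model of the deposited counts on diet, with an F test on 13 residual degrees of freedom, a dispersion of at least 1 and Benjamini-Hochberg adjustment at 0.05. The same test was run on counts summed over windows of 1000 bp holding at least 3 listed CpGs. Values with 1 number per library (mean methylation, ribosomal DNA, gene lists) were compared with an exact two-sided permutation test over all 6435 splits of the libraries, whose smallest possible p is 0.000155. Intervals of differences were obtained at the 95% level by inverting that test. On simulated data made from the real depths and levels, with 200 changed units, the CpG test recovered 0% of units that fell by 5 or 10 points, 54.5% at 20 points and 92% at 30 points, among 204492 CpGs. For the windows, 38% were recovered at 5 points, 88.5% at 10, 98% at 20 and 100% at 30, among 28743. The simulation drew the changed units only from those above a minimum methylation, and 89.7% of all listed positions have a mean of at least 90%. Rates for units of intermediate methylation were not computed apart. The simulation only lowered levels and kept every listed CpG. A real fall could leave a CpG with fewer than 11 methylated reads in a library and so unlisted. These rates therefore hold mostly for highly methylated listed positions and can overstate what the list can show.

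The rule for named units, the gene lists, the tests and the coverage minimum were set before the data were examined. CpGs past an adjusted p of 0.05 with a difference of at least 10 points are named, 10 in each direction, and where fewer pass the places are filled by the smallest p in that direction, 1 unit per gene. Gene names come from a RefSeq table of the same build, GRCm38.p6, which gives gene spans but neither strands nor exons. A unit was named by the gene whose span, or 2 kb on either side, holds it. Exon, intron and UTR positions were not analysed here. The gene lists had been planned on promoters. Without strands, CpGs within 1 kb of either end of a gene were used in their place, except for imprinted genes, whose strand is general knowledge. Maternally methylated imprints were taken at their planned promoters. Paternally methylated imprints were taken, as planned, in regions upstream of the gene, up to 5 kb for H19, up to 20 kb for Meg3 and Zdbf2, and from 20 to 40 kb for Rasgrf1, so their values are neither promoter nor gene-end values. This choice, and the version with whole genes and 2 kb flanks, were made after the files were seen.

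Ribosomal DNA is present in many copies that the assembly mostly leaves out. In mm10 its reads were found at Rn18s-rs5 on chromosome 17, the only gene of the 45S unit in the gene table, and its CpGs form the planned ribosomal DNA result. The surrounding block is spanned by CpGs no more than 1000 bp apart and at least 5 times the median depth. Shallower CpGs lying between them were kept in it. This block, and blocks on chromosomes 6 and 16 with similar behaviour, were added after the data were seen. No genome sequence was used here, so these blocks were not matched to the ribosomal repeat by sequence.

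Alternatives were coverage minimums of 5 and 20, removal of positions above the 99.9th percentile of coverage, autosomes, positions with a mean of 10 to 90 percent, limma on percentages, on centred percentages and on logit values with pseudocounts of 1 and 0.1, other window sizes, coverage-weighted means, each library left out in turn, and averages over runs of consecutive title numbers (or, for CpGs, limma with the runs as a block). Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.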

Results

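Methylation was measured at 204492 CpGs in 7 control and 8 protein restricted libraries of mouse sperm. The comparison of interest is protein restricted against control, with ribosomal DNA, named in the title of the series, as the first locus. Counts summed over the listed CpGs ran from 7846118 to 11841657 in control libraries and from 6650912 to 10712016 in protein restricted libraries, with a median coverage per CpG of 26 to 42 reads. Over all listed CpGs sperm DNA was highly methylated, with 89.7% of positions at a mean of 90% or more and 2008 positions under 50%. The listed positions lay within a gene span for 61.7%, and 1563 were on the X chromosome and 155 on the Y chromosome. Because positions with few methylated reads in any library are not listed, unmethylated promoters are hardly represented.

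Ribosomal DNA, the multi-copy genes for ribosomal RNA, was partly methylated and varied widely between libraries. At Rn18s-rs5 (mm10 chromosome 17, 39846354 to 39848202), annotated as a pseudogene related to the small-subunit ribosomal RNA gene, 102 CpGs averaged 41.3% ± 7.70 (SD, n = 7) in control and 44.5% ± 4.44 (SD, n = 8) in protein restricted sperm. The mean coverage of these CpGs was 1206 reads, between 898 and 1803 in single libraries. The difference of 3.20 points was smaller than the spread between libraries (exact two-sided permutation p = 0.328, 95% interval -3.80 to 9.87). Of the 102 CpGs 89 had a higher mean in protein restricted sperm and 13 a lower one, which are not independent, and none passed the quasi-binomial test, with 3 at an unadjusted p under 0.05.

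The estimate depended on single control libraries. Control replicate 3 had 54.7% at Rn18s-rs5, the highest of all libraries, and without it the difference was 5.45 points (exact permutation p = 0.0656). Without control replicate 4 it was 1.79 points (exact permutation p = 0.577), and with runs of consecutive title numbers averaged it was 4.81 points (exact permutation p = 0.314). Over the surrounding block of 372 CpGs (39843014 to 39848698), which was added after the data were seen, control sperm averaged 30.9% ± 9.79 (SD, n = 7) and protein restricted sperm 34.4% ± 5.64 (SD, n = 8). That difference of 3.45 points had an exact permutation p of 0.413, and without control replicate 3 it was 6.66 points with a p of 0.0503 by the exact permutation test. It was 1.87 points without control replicate 4 and 2.06 points without control replicate 5.

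**Figure D1:**
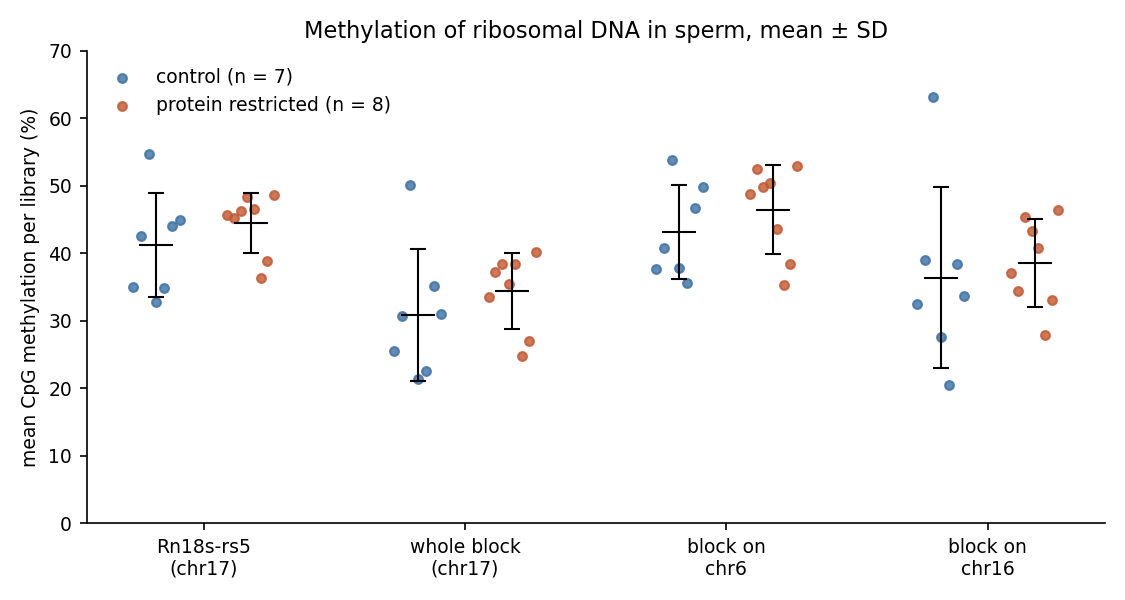
Mean CpG methylation per library (y axis, percent) in Rn18s-rs5, the whole block on chromosome 17, and the blocks on chromosomes 6 and 16, for 7 control and 8 protein restricted libraries. Each point is a library, and the bars give the mean and SD of each diet. The highest control library in the whole block, at 50.1%, lies above all protein restricted libraries, which range from 24.8% to 40.2%.

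Levels varied along the block in both diets. The part upstream of Rn18s-rs5 (221 CpGs) averaged 27.0% ± 10.7 (SD, n = 7) in control and 31.2% ± 6.64 (SD, n = 8) in protein restricted sperm (exact permutation p = 0.378), and the 49 CpGs downstream 26.8% ± 10.8 (SD, n = 7) and 27.7% ± 5.22 (SD, n = 8) (exact permutation p = 0.855). Without control replicate 3 these differences rose from 4.13 to 7.65 points (exact permutation p = 0.0486) and from 0.922 to 4.71 points (exact permutation p = 0.1002), and the downstream difference was -0.639 points without control replicate 5, -0.521 without control replicate 4 and -0.219 without protein restricted replicate 3. Methylation at single CpGs of the block, averaged over all libraries, ran from 4.88% to 73.7%. The median dispersion of the block's CpGs was 32.7, where counting noise alone gives 1. The 6 regions compared include blocks on chromosomes 6 and 16 that were not matched to the ribosomal repeat by sequence. Over these regions the lowest Benjamini-Hochberg adjusted p was 0.620 (exact permutation tests), and without control replicate 3 it was 0.120. That adjustment does not cover the choice of the library left out. Control replicate 3 was the highest library in each region, so leaving it out had to raise the difference.

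**Figure D2:**
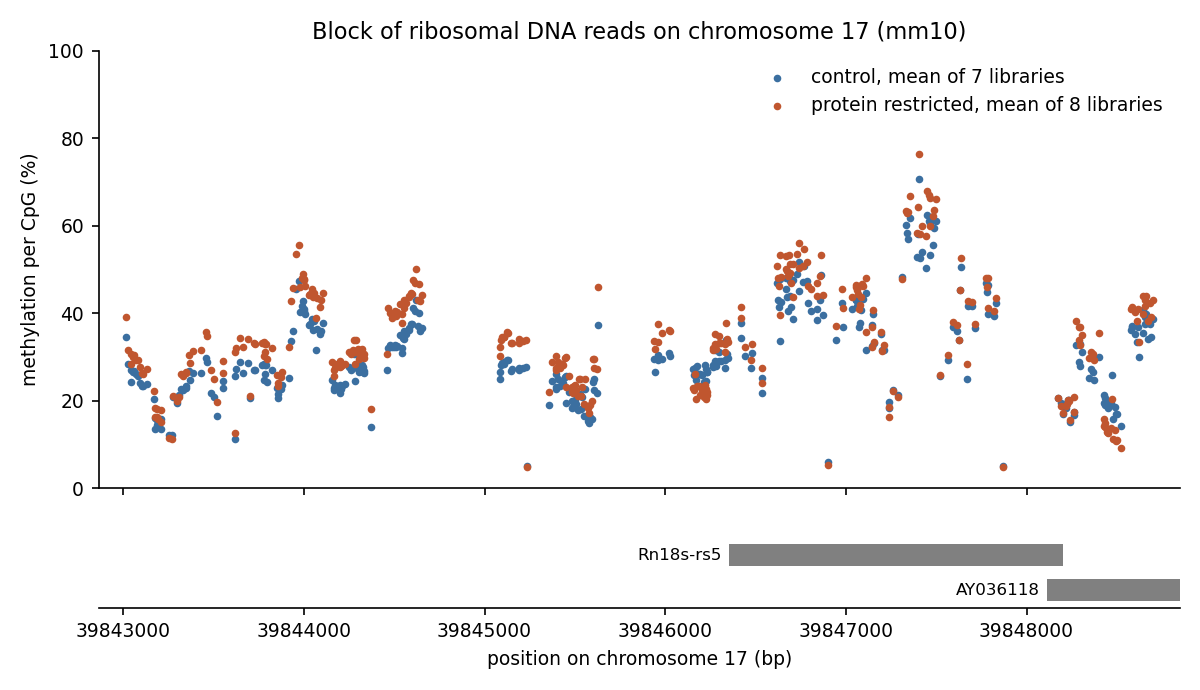
Methylation of each CpG (y axis, percent, mean of the libraries of a diet) along the block on chromosome 17 (x axis, mm10 position), with the spans of Rn18s-rs5 and the long noncoding RNA AY036118 drawn below. The highest CpGs lie inside Rn18s-rs5, and the means of the diets differ by -6.23 to 9.96 points at single CpGs.

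Blocks on chromosome 6 (3201231 to 3201576, 23 CpGs) and on chromosome 16 (57391288 to 57391501, 15 CpGs, within Cmss1 and Filip1l) had mean coverages of 2624 and 977 reads. On chromosome 6 control sperm averaged 43.2% ± 6.96 (SD, n = 7) and protein restricted sperm 46.5% ± 6.63 (SD, n = 8), and on chromosome 16 the values were 36.4% ± 13.4 (SD, n = 7) and 38.6% ± 6.53 (SD, n = 8). The exact permutation p was 0.355 and 0.709. Without control replicate 3 the differences rose from 3.30 to 5.06 points (exact permutation p = 0.155) and from 2.15 to 6.61 points (exact permutation p = 0.0926), and without control replicate 5 they were 2.03 and -0.496 points. Methylation of the chromosome 17 block correlated with that of the chromosome 6 block over the 15 libraries (Pearson r = 0.859, permutation p = 6.0e-05, Spearman rho = 0.868, permutation p = 9.0e-05) and with that of the chromosome 16 block (r = 0.927, permutation p = 1e-05, the smallest 100000 permutations can give, rho = 0.929, permutation p = 3.0e-05). Adjusted over the 4 relations computed across libraries, these p-values were 0.000120 and 4.0e-05. Leaving out the 2 libraries farthest from the median, r was 0.865 and 0.872. Within control r was 0.888 and 0.964, and within protein restricted 0.858 and 0.846. The chromosome 17 block also followed the mean methylation of the 204082 CpGs outside these blocks (r = 0.830, permutation p = 0.000180, adjusted p = 0.000240, rho = 0.732, permutation p = 0.00300). That r was 0.708 without the 2 farthest libraries, 0.927 within control (exact permutation p = 0.00238) and 0.680 within protein restricted sperm (exact permutation p = 0.0572).

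**Figure D3:**
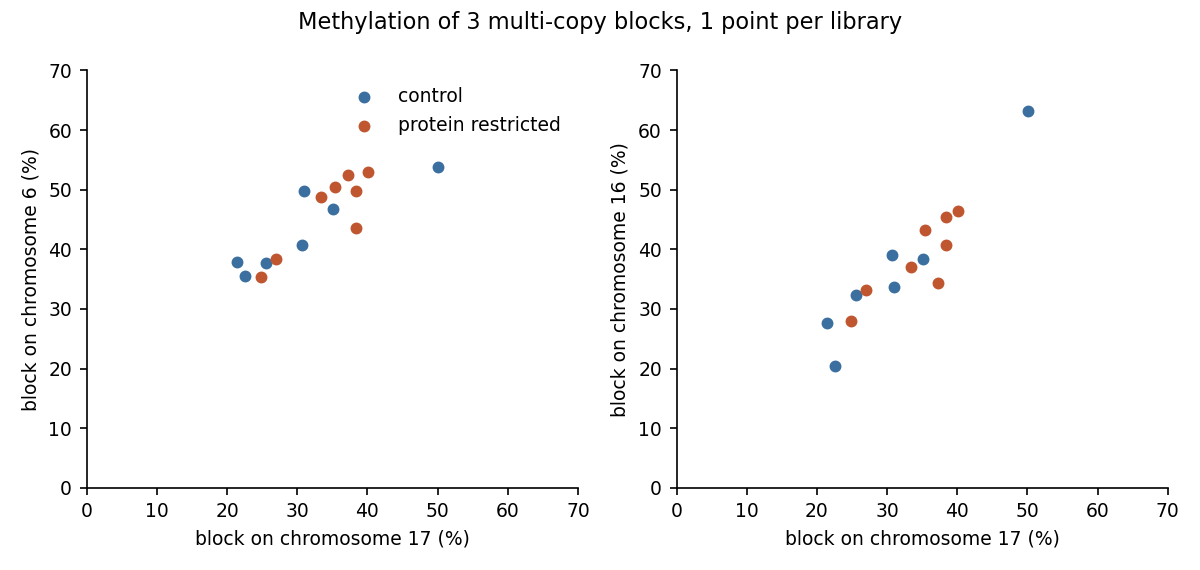
Mean methylation of the chromosome 6 block (left, y axis, percent) and of the chromosome 16 block (right, y axis, percent) against that of the chromosome 17 block (x axis, percent), 1 point per library and coloured by diet. The Pearson correlations are 0.859 and 0.927.

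Mean methylation over all CpGs was 95.3% ± 0.145 (SD, n = 7) in control and 95.3% ± 0.0944 (SD, n = 8) in protein restricted sperm. The difference was 0.0118 points (exact two-sided permutation p = 0.848, 95% interval -0.125 to 0.144), and its sign changed without protein restricted replicate 4 (-0.00289), control replicate 4 (-0.0105) or control replicate 5 (-0.0189). Weighted by coverage, which gives the deepest repeats the most weight, the difference was 0.964 points (exact permutation p = 0.356). The weights were each library's own read counts, so this value also depends on how each library's reads were spread over deep repeats. It does not measure a difference in methylation alone.

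Among single CpGs, the quasi-binomial test called 0 of 204492 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 7754 CpGs, or 3.79%, of which 3870 were higher and 3884 lower in protein restricted sperm. limma called 0 on percentages, with 9320 at an unadjusted p under 0.05, and 0 on logit values with a pseudocount of 1, with 9321. With a pseudocount of 0.1 it called 10, all of them CpGs at which a diet was at 100% in every library. A difference of 10 points or more was seen at 248 CpGs and of 20 points at 0. The test recovered 54.5% of simulated falls of 20 points at listed CpGs, mostly highly methylated ones. A real fall of that size could leave fewer than 11 methylated reads in a library and so keep a CpG off the list. Neither value speaks for such CpGs. Of 28743 windows of 1 kb, 0 passed and 957 had an unadjusted p under 0.05, with 470 higher and 487 lower. limma called 0 windows on percentages and 2 on logit values with a pseudocount of 0.1. The window test recovered 88.5% of simulated falls of 10 points, with the same limit.

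**Figure D4:**
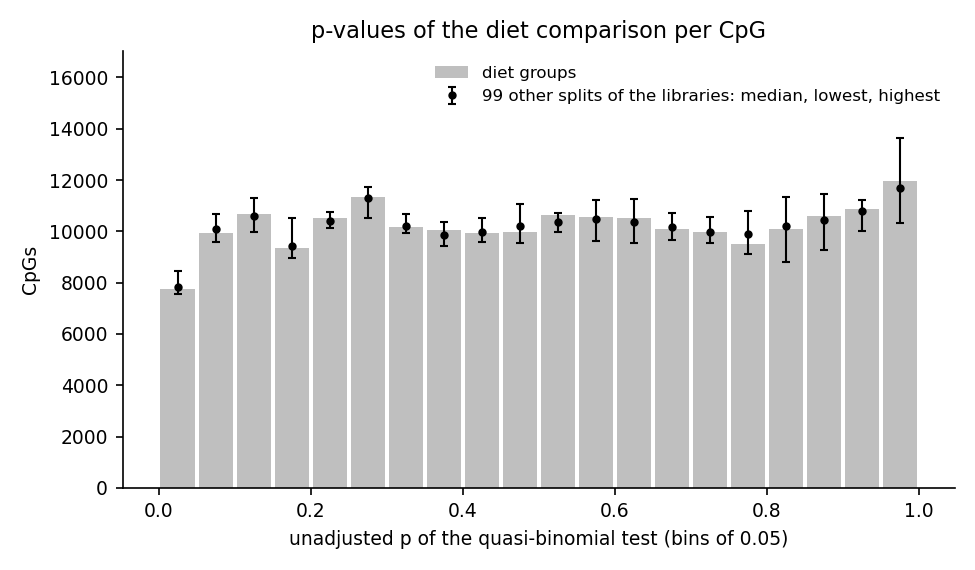
Number of CpGs (y axis) in bins of the unadjusted p of the quasi-binomial test (x axis) for the diet groups (bars), with the median and the lowest and highest counts over other splits of the same libraries (points and lines). The lowest bin holds 7754 CpGs for the diets and between 7543 and 8466 for the other splits.

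None of the CpGs with the smallest p passed. Higher in protein restricted sperm was a CpG in Ank3, which encodes the membrane scaffold ankyrin G (chromosome 10, 69657316), at 88.2% ± 3.67 in control and 95.9% ± 3.38 in protein restricted sperm. A CpG in Prdm6, a gene of a PR domain transcriptional repressor, was at 94.0% ± 3.07 and 100% in every protein restricted library, and a CpG in Ell, an RNA polymerase II elongation factor, at 96.0% ± 3.10 and 100%. CpGs in B4galnt3 and within 2 kb of Eif2ak3, which encodes a kinase of the unfolded protein response, were at 97.4% ± 1.13 and 93.6% ± 3.66 in control and at 100% in protein restricted sperm. The largest difference among the CpGs named as higher was 18.1 points, in Gm38424 on chromosome 5. The remaining 4 lay outside genes on chromosomes 2, 9, 12 and 19.

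On the lower side, 9 of the 10 CpGs were at 100% in every control library. In Rarb, the gene of a retinoic acid receptor, a CpG on chromosome 14 (17064245) was at 94.0% ± 4.41 in protein restricted sperm. A CpG in Rora, a nuclear receptor of the circadian clock, was at 96.5% ± 3.33, in Dnah2, an axonemal dynein heavy chain, at 97.1% ± 2.54, in Gabbr2, a subunit of the GABA-B receptor, at 97.3% ± 2.13, and in Gm30075 at 94.9% ± 2.89. The adjusted p of each named CpG was 1 in the quasi-binomial test. Mean coverage at the named CpGs lying in or within 2 kb of genes ran from 24.7 reads at Rarb to 78.2 at B4galnt3.

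Ank3 and a locus on an unplaced scaffold were named both as CpGs and as windows. Each of these windows holds the named CpG, so the namings share reads and are not independent. The scaffold CpG was deep, with a mean coverage of 1061 reads. On the scaffold, the CpG at 59103 was at 4.09% ± 0.402 in control and 2.99% ± 0.537 in protein restricted sperm, and the window from 59001 to 60000 at 3.76% ± 0.407 and 3.01% ± 0.131. The Ank3 window (chromosome 10, 69657001 to 69658000, 4 CpGs) was at 91.9% ± 2.57 in control and 96.4% ± 1.13 in protein restricted sperm, higher than the control mean in all 8 protein restricted libraries, with an unadjusted p of 0.000210 and an adjusted p near 1 in the quasi-binomial test. Also higher without passing were windows in Larp6 (82.4% ± 4.19 and 90.3% ± 3.79), in Lpin1, a phosphatidate phosphatase of lipid synthesis (76.9% ± 3.13 and 83.5% ± 3.76), in Sgms2, a sphingomyelin synthase (93.2% ± 2.75 and 97.8% ± 1.30), in Phactr1 and in Grk3. Lower without passing were windows in Plekhg1 (97.6% ± 2.11 and 91.3% ± 1.85), Kif16b, a kinesin (100% and 98.4% ± 0.501), Plekhh1, Cd24a and within 2 kb of Ccdc6. A window on chromosome 4 outside genes (130200001 to 130201000) had the largest difference among the named windows, 77.4% ± 4.76 in control against 67.1% ± 4.39.

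Of the fixed gene lists, none passed the test between diets. At gene ends, or upstream regions for paternal imprints, 10 lists held at least 3 listed CpGs, and the lowest adjusted p over them was 0.868 (exact permutation tests, Benjamini-Hochberg). Imprinted genes methylated on the maternal copy had 0 of 23 promoters listed. Paternally methylated imprint regions, which are methylated in sperm, had 7 CpGs, up to 20 kb upstream of Meg3 and 20 to 40 kb upstream of Rasgrf1, at 95.5% ± 1.09 (SD, n = 7) in control and 94.3% ± 1.42 (SD, n = 8) in protein restricted sperm, with 1 CpG higher and 6 lower (exact permutation p = 0.0948). Germline genes had CpGs at 2 of 18 genes. At Sycp1, a synaptonemal complex gene, the CpG was at 33.4% ± 3.95 and 32.5% ± 6.82, and at Piwil1, a gene of the piRNA pathway, the 2 CpGs were at 98.4% ± 1.32 and 98.4% ± 1.29.

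Ribosome biogenesis genes had 11 CpGs at 3 of 22 genes, 5 higher and 6 lower (exact permutation p = 0.676). Those at Taf1d, a factor of RNA polymerase I, were at 86.1% ± 1.04 and 86.9% ± 1.71, those at Polr1c, a subunit of RNA polymerases I and III, at 51.7% ± 5.72 and 50.5% ± 3.92. Metabolic and growth genes had 4 CpGs at 2 of 26 genes, Igf2 and Igf1r, 1 higher and 3 lower (exact permutation p = 0.309). DNA methylation and chromatin genes had 6 CpGs, at Uhrf1 and Dppa3 (p = 0.762 in the exact permutation test), and pluripotency genes 3 CpGs at Esrrb (p = 0.644 in the exact permutation test). Hox clusters had 5 CpGs at 4 of 43 genes (p = 0.868 in the exact permutation test), among them Hoxb1 at 40.8% ± 7.06 and 39.8% ± 7.54. Olfactory and vomeronasal receptors had 170 CpGs at 94 of 1783 genes, 90 higher and 80 lower (p = 0.453 in the exact permutation test). Clustered protocadherins had 2 CpGs and were not tested.

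Spermatogenesis genes had 9 CpGs at Prm1 and Ldhc, 5 higher and 3 lower (exact permutation p = 0.417). Of these, 2 CpGs passed when adjusted over the list alone and 0 over all CpGs. Both lie near Prm1, which encodes a protamine that packs sperm DNA (chromosome 16, 10796685 and 10796709), at 96.6% ± 5.77 and 96.1% ± 5.20 in control and 100% in every protein restricted library, with mean coverages of 17.7 and 17.8 reads. Over whole genes with 2 kb flanks, a region chosen after the data were seen, 12 lists were tested and the lowest adjusted p was 0.830. In that region 0 of 27 spermatogenesis CpGs passed when adjusted over the list alone.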

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

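Of the tests in this part, those on deep repeats, on depth and on the mean of other CpGs were chosen after the results were seen, and the test on imprint CpGs before.

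Over 100 groups of libraries examined, 7 held a library whose gap to the nearest other was large against the range of its diet. Chance gives about 1 in 20, but this rate does not hold for units at 100% or for units named by their small p. In the 49 CpGs downstream of Rn18s-rs5, control replicate 3 was at 49.5%, against 17.4% to 27.7% in the other control libraries. Control replicate 4 had 11841657 counts, against 7846118 to 9333437 in the other control libraries. At the ends of germline genes control replicate 7 was at 73.8%, against 76.3% to 78.2%. At the named CpG on chromosome 2 control replicate 5 was at 72.2%, against 89.7% or more. At the Rarb CpG protein restricted replicate 6 was at 84.6%, against 92.9% or more. In the Phactr1 window protein restricted replicate 1 was at 98.1% and in the Grk3 window protein restricted replicate 7 at 98.8%, where the other protein restricted libraries were at 100%. With all others at 100%, any lower value would have been flagged.

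Ribosomal DNA methylation of the whole block spread widely between control libraries, from 21.4% to 50.1% (21.4% to 35.1% without control replicate 3, which lowers the control SD from 9.79 to 5.38 points and the within-diet SD from 7.84 to 5.53), and it rose and fell over the libraries with the mean of all other CpGs (r = 0.830). A library-wide difference in conversion or calling is argued against as the whole cause, since 8 other deep repeat windows of intermediate methylation had a median within-diet SD of 1.28 points (highest 3.43) and the 20718 other CpGs at 10 to 90% moved by 0.0598 points per point of ribosomal DNA, but a factor shared with the rest of the genome stays open. Cells of another type stay open too, because the 7 CpGs upstream of Meg3 and Rasgrf1 ranged over only 4.45 points but their level in other cells was not measured, and the bound set for them overlooked that positions are listed only with at least 11 methylated reads in every library. Depth stays open, since the Pearson correlation of relative depth and methylation was -0.418 (permutation p = 0.121, Spearman rho = -0.414, permutation p = 0.126), was -0.158 without the 2 libraries farthest from the median depth, and lay at -0.445 within control and -0.615 within protein restricted sperm. Differences between samples in the number of ribosomal DNA copies were examined only through this relative depth (block depth over median depth), which leaves them open. Differences in the sequence of the copies are a further candidate explanation that was not tested.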

How the results depend on the processing

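The whole ribosomal DNA block, the lists over whole genes, the counts at an unadjusted p and the correlation of deviations were chosen after the data were seen. In the counts, limma on logit values with a pseudocount of 0.1 gave 10 CpGs and 2 windows against 0, and each of these had a diet at 100% in every library, where this pseudocount sets the size of the logit. Every other setting run for CpGs and windows called 0, as did each fit with a library left out. The ribosomal DNA difference kept its direction and stayed above 0.05 in all settings run, with p from 0.0656 to 0.577, between 1.79 and 5.45 points as libraries were left out (whole block 1.87 to 6.66, p from 0.0503 to 0.663). The mean methylation difference ran from -0.0189 to 0.0529 points as libraries were left out, with a change of sign without protein restricted replicate 4 and without control replicates 4 and 5, and weighting by coverage gave 0.964 points (exact permutation p = 0.356). Weights were each library's own read counts, so weighted differences, also those of gene lists, mix methylation with where a library's reads fell. The correlation of libraries within runs of title numbers exceeded that between runs by 0.000178 (permutation p = 0.40), and by 0.0185 (p = 0.0285 by permutation) with deviations from the diet mean, or 0.0156 (permutation p = 0.0205) outside ribosomal DNA. The correlations of deviations were negative both within runs and between them. Subtracting the mean of a diet's own libraries makes them negative on average, so their sign is not a result. The cause of the excess within runs was not tested. Gene lists never passed, but signs of small differences changed. For DNA methylation genes the difference was 0.222 at a coverage minimum of 20, 0.0282 with weighting, 0.0822 over whole genes and -0.447 to 0.0932 as libraries were left out. For Hox clusters it was -1.18 with weighting, -0.127 with runs averaged and -0.502 to 0.730 as libraries were left out. For ribosome biogenesis it was -0.192 within 2 kb of gene ends and -0.0326 to 0.442 as libraries were left out, for germline genes -0.760 to 0.167 likewise. For pluripotency it was 0.299 within 2 kb and 0.112 over whole genes, for metabolic genes 0.0978 and for paternal imprints 0.165 over whole genes. Paternal imprints were taken upstream of the genes, so the distances from gene ends do not test them. A coverage minimum of 20 left 3199 CpGs at an unadjusted p under 0.05, and a mean methylation of 10 to 90 percent left 648, against 7754. Both settings tested fewer CpGs and shares were not computed for them, so the lower counts alone show no change in the result. The minimums of 5 reads and 5 libraries per diet removed nothing, so they say nothing about stability. No paired analysis was possible because the replicate numbers were given in accession order and the diets share no label number.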

Other observations

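Of the tests in this part, those on ribosomal DNA and on deviations from the diet mean in runs of title numbers, on the blocks of chromosomes 6 and 16 and on the number of CpGs at an unadjusted p under 0.05 were chosen after the results were seen, as was the ranking of windows by spread.

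Apart from ribosomal DNA, some windows varied between libraries of a diet by far more than the counting noise computed for independent calls. Ranked by within-diet SD after removing counting noise, a window in Kcnd2, a voltage-gated potassium channel gene (chromosome 6, 21393001 to 21394000), came first, with libraries from 34.8% to 83.6% and a within-diet SD of 14.8 points (7.94 in control and 18.8 in protein restricted sperm, a difference in spread that was not tested) against 3.40 expected from counting. Windows in B230219D22Rik (30.3% in control replicate 4, otherwise 47.2% to 75.5%), within 2 kb of n-R5s28, a gene named for 5S ribosomal RNA (45% to 85.8%), and in Slc16a6, a monocarboxylate transporter gene (60% to 98.9%), were also among the first. None passed the quasi-binomial test between diets. In the median window the within-diet SD was 1.34 points and that expected from counting 1.31, and 595 of 28743 windows had an excess SD over 5 points. The expected SD treats calls at CpGs of the same read as independent. It can therefore be too low, and the number of windows with an excess too high.

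The blocks on chromosomes 6 and 16 followed ribosomal DNA over the libraries, with the smaller Pearson correlation at 0.859, and their depth was many times the median. They may hold reads of the same multi-copy source placed elsewhere in the assembly, a hypothesis found and tested on the same data. A correlation of this size is not specific to them, since the mean of all CpGs outside these blocks also followed ribosomal DNA, with r = 0.830.

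Libraries with neighbouring title numbers may share something besides diet, as a hypothesis. The mean correlation of deviations from the diet mean was -0.138 within runs of consecutive numbers and -0.157 between them. Subtracting the mean of a diet's own libraries makes such correlations negative on average, so only their difference is read here. A random order of libraries gave a difference as large in a share of 0.0285 of reorderings, and outside ribosomal DNA the difference was 0.0156. For the ribosomal DNA block all runs together gave a share of 0.224, with no common direction. Libraries of a protein restricted run differed by 2.58 points against 7.34 otherwise (share 0.0256), and those of a control run by 12.4 points against 10.6 (share 0.718). Over the 12 such tests the lowest adjusted p was 0.0855, and limma's consensus correlation within runs was -0.0321, so the data do not settle it. Shared litter and shared handling cannot be separated, since the labels do not say what the numbers mean.

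Chance could not be excluded for the number of CpGs at an unadjusted p under 0.05, since 74 of 100 splits of the libraries, the real one included, gave at least the 7754 CpGs of the diets, and the highest of the others was 8466. For the counts of CpGs and of windows at an adjusted p under 0.05 the comparison decides nothing, because the diets gave 0, which all 100 splits reach, and the highest of the others was also 0.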
